A study of Mus musculus with 30 samples.

How the data were processed

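The deposited count table gave whole-number counts per gene for 24557 gene entries and 30 libraries, with a symbol, a numeric gene identifier, an alias and a description for each entry. Per the submitters' processing notes, the tools were cutadapt, FastQC 0.11.9, STAR 2.7.10a, HTSeq 0.11.1, R 4.1.0 and edgeR 3.34.0 with the mm10 genome build; the notes do not state the role or settings of each tool. Per the labels' protocols, RNA was isolated with a NucleoSpin kit, polyadenylated RNA was used and libraries were made with a TruSeq kit; whether the libraries were stranded is not stated. The second deposited table held log2 values of 14877 genes; its name calls them TMM-normalized counts. Log2 CPM values recomputed from the counts over these genes, with TMM (trimmed mean of M-values) factors and a prior count of 2, matched the deposited log2 values within 5e-05, under a tolerance of 1e-04. The low-count filter behind that table is not stated.

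Everything else was computed here from the counts, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Samples were grouped by treatment (mXTX301, unmasked control, vehicle) and day (4, 7) from the labels, with 5 libraries in each of 6 groups. Of the 24557 gene entries, 5 carried a symbol already present and were dropped, leaving 24552. The groups, tests, gene lists, gene panel, naming rule and most alternatives were chosen before the data were examined. Genes were kept with the edgeR function filterByExpr, leaving 15482 for testing. One mean per group was fitted to all 30 libraries with TMM factors and robust quasi-likelihood dispersions (24 residual degrees of freedom; common biological coefficient of variation 27.3%; median prior degrees of freedom 3.54). Each comparison was a contrast of group means tested with the edgeR quasi-likelihood F test, adjusted over 15482 genes with the Benjamini-Hochberg method and called at an adjusted p under 0.05. The change of a drug effect between days was the contrast of the day 7 and day 4 drug-minus-vehicle differences. No replicate term was fitted, because replicate numbers did not pair libraries across groups: pairs with the same number had a mean r of 0.0436 over 2000 genes, other pairs -0.00442, and 9 of 30 libraries had their best partner in their own number.

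Gene lists were tested with camera on the edgeR fit, with a preset inter-gene correlation of 0.01 and adjustment over the lists; the same test with an estimated correlation and the rotation test fry were alternatives. Member counts were taken from the gene test over all genes and were also adjusted over the list alone. The level of a list in a library was the mean log2 CPM of its members (prior count 2). Levels were compared by a two-sided exact permutation test of 5 against 5 libraries (252 regroupings, smallest p 0.00794), adjusted over the lists, with a 95% interval of the difference from the exact Wilcoxon procedure. Changes of a drug effect on a list level between days were tested by a two-sided exact permutation test that regrouped the days within the drug and within vehicle (63504 regroupings), adjusted over the lists. The 39 tested lists were interferon-gamma response, interferon-inducible GTPases, type I interferon response, MHC class I presentation, MHC class II presentation, cytotoxic effectors, T cells, NK cells, IL-12 and IL-18 signalling, regulatory T cells, inhibitory receptors and ligands, T cell-attracting chemokines, lymphoid aggregate chemokines, B cells and plasma cells, macrophages, alternatively activated macrophages, monocytes, neutrophils, acute inflammatory cytokines, conventional dendritic cells, migratory dendritic cells, plasmacytoid dendritic cells, mast cells, programmed cell death, cell cycle, MYC targets and ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation, cholesterol biosynthesis, unfolded protein response, fibroblasts and collagen, endothelium, epithelial markers, skeletal muscle, skin epithelium, adipocytes, erythroid cells, ribosomal proteins, and dissociation and early stress. A list of 13 mitochondrial transcripts was also fixed, but the table held none of its members and it was not tested. Tested members were 5 of 12 for lymphoid aggregate chemokines, 5 of 13 for erythroid cells, 8 of 17 for B cells and plasma cells, 11 of 16 for epithelial markers, 12 of 15 for NK cells and 19 of 22 for T cells, where Trac, Trbc1 and Trbc2 were absent from the table. Eno1, Krt8, Krt18, H2-Q7, Ly6g and the haemoglobin genes had near-zero counts, so their own levels were not read from this table.

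Named genes followed a fixed rule. A panel of 26 genes was read in every drug comparison. The 5 largest rises and 5 largest falls were added among called genes with a mean of at least 1 CPM and all 5 libraries of either group beyond the other group (the 3 largest each way for time and interaction comparisons, without that last condition). Up to 4 members with the smallest p were named per list. Predicted genes, clone names and receptor or antibody segments were left out. Some genes that the rule selects are not reported here. CPM values are group means with SD over 5 libraries, and log2 fold changes carry the standard error of the edgeR fit. Coordinates were taken by symbol from a GENCODE M21 annotation of the mm10 build.

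The drug responses were compared by the Pearson r and covariance of differences in mean log2 CPM against the shared vehicle libraries. These were set beside values with the vehicle libraries split 2 and 3 between the drugs and beside 20 simulations without a drug effect. No p was attached to r.

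The alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of 1 CPM in 5 libraries, a replicate block, the DESeq2 Wald test, limma-voom, limma-trend on the authors' log2 table, a fit of only the groups compared, a prior count of 0.5 for levels, estimated correlation, fry, and leaving out each library in turn. The authors' table was planned as log2 of value plus 1; its values were already on a log2 scale and were used as they were. Fits without the skin-rich libraries, and with skin and muscle list levels as covariates, were added after the data were seen. Libraries were called skin-rich at a skin epithelium level of 2 or more.

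The gene test was run on simulated counts with the real means and depths, in which 200 genes were changed 1.5-, 2- or 4-fold. For mXTX301 against vehicle at day 4 recovery at those sizes was 68.7%, 95.5% and 100%, with 4.86% false calls. At day 7 it was 68.7%, 89.6% and 98.5%, with 1.72% false. For the unmasked control against vehicle at day 4 it was 73.1%, 88.1% and 97%, with 2.82% false. At day 7 it was 73.1%, 91% and 93.9%, with 2.82% false. For mXTX301 against the unmasked control at day 4 it was 53.7%, 76.1% and 98.5%, with 5.59% false. At day 7 it was 62.7%, 76.1% and 97%, with 4.27% false. For vehicle over time it was 71.6%, 83.6% and 95.5%, with 4.57% false. For the change of the mXTX301 effect it was 41.8%, 73.1% and 90.9%, with 5.52% false, and for the unmasked effect 43.3%, 77.6% and 97%, with 5.84% false. Of 20 unchanged lists, 0 were called.

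These splits numbered 100 per comparison, the real one included. Raw reads, alleles, splicing and isoforms were not analysed here.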

Results

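Polyadenylated RNA was sequenced from subcutaneous tumours of MC38, a mouse colon carcinoma line, grown in female C57BL/6J mice. Mice received a single intravenous dose of mXTX301, a masked interleukin-12 surrogate for mice, at 0.39 mg/kg, of an unmasked positive control at 0.03 mg/kg, or of vehicle, and tumours were taken at day 4 or day 7. Interleukin-12 is a cytokine that drives T cells and natural killer (NK) cells to make interferon-gamma. Each of the 6 groups held 5 libraries from different mice, 30 in all. Total counts per library ranged from 48.3 M to 85.2 M. At day 4 the group means were 58.9 ± 6.2 M for vehicle, 56.5 ± 6.29 M for mXTX301 and 63.3 ± 13 M for the unmasked control (SD, n = 5). At day 7 they were 69.4 ± 8.35 M, 58.4 ± 7.34 M and 63.2 ± 3.31 M in the same order. After the low-count filter 15482 genes were tested. Epidermal genes such as Krt5, Krt1 and Krt14 led the first principal component, which held 43.4% of the variance of the 1000 most variable genes. Skin-rich libraries numbered 2 in each day 7 drug group and 1 in each other group.

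The comparison of mXTX301 with vehicle at day 4 asked how the tumour transcriptome differed 4 days after the masked cytokine. Ifng, which encodes interferon-gamma (gene 15978; mm10 chromosome 10, 118441046 to 118445892, plus strand), rose 20.6-fold, from 0.251 ± 0.215 to 5.17 ± 3.39 CPM (SD, n = 5; edgeR adjusted p = 3.78e-06). Genes induced by interferon-gamma rose with it: Gbp2b, a guanylate-binding protein gene (gene 14468; chromosome 3, 142594847 to 142619179, plus strand), rose 87.7-fold, from 0.254 ± 0.129 to 22.6 ± 10.8 CPM (adjusted p = 1.53e-07). Cxcl9, a chemokine gene whose product attracts activated T cells, rose 6.11-fold, from 27 ± 6.17 to 165 ± 33.2 CPM (adjusted p = 1.91e-08). Cd8a, which encodes a chain of the cytotoxic T-cell co-receptor (gene 12525; chromosome 6, 71373427 to 71379173, plus strand), rose 6.30-fold (adjusted p = 0.000565). In all, 2505 genes were higher and 2477 lower, 32.2% of those tested, and 618 of the higher and 89 of the lower genes changed at least 2-fold. In 1438 higher and 1444 lower genes the groups did not overlap, 18.6% of genes against 0.794% by chance. Leaving out the skin-rich libraries gave 1843 higher and 2118 lower.

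Of the panel of 26 genes, 18 rose and 0 fell at day 4 of mXTX301 (21 and 0 adjusted over the list alone). Irf1, a transcription factor gene of the interferon-gamma response, rose 2.07-fold (adjusted p = 6.65e-11). Ciita, the master regulator of MHC class II genes, rose 8.02-fold (adjusted p = 2.24e-08). Il12rb2, a subunit of the interleukin-12 receptor, rose 10.8-fold (adjusted p = 4.39e-06), and Tbx21, the T-helper 1 transcription factor gene, rose 5.39-fold (adjusted p = 0.000113). Cd274, which encodes PD-L1, rose 3.32-fold, Ido1, a tryptophan-degrading enzyme gene, 5.01-fold and Socs1, a feedback inhibitor of cytokine signalling, 1.68-fold. Nos2 and Arg1, arginine-metabolizing enzymes of myeloid cells, rose 4.82-fold and 3.06-fold. The killing genes Gzmb and Prf1 rose 2.53-fold (adjusted p = 0.0161) and 3.94-fold (adjusted p = 0.00551), and the NK receptor gene Ncr1 2.44-fold (adjusted p = 0.0432). mXTX301 replicate 3 led Cd8a, Gzmb and Prf1 (33.7, 69.7 and 55.3 CPM, others up to 9.36, 33 and 21.7). Gzmb and Prf1 overlapped vehicle. Cxcl10 (adjusted p = 0.131), Cd4 (0.317), Foxp3 (0.991), Il10 (0.0736), S100a8 (0.0549), Mki67 (0.285), Col1a1 (0.675) and H2-K1 (0.054) did not pass. Besides Gbp2b and Ifng, the largest rises were Gbp10 at 17.5-fold, the lymphocyte adhesion receptor gene Cd226 at 15-fold and the macrophage scavenger receptor gene Marco at 14.1-fold (adjusted p = 0.0105).

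Genes also fell at day 4 of mXTX301. Mest, an imprinted gene (gene 17294; chromosome 6, 30723547 to 30748465, plus strand), fell by 2.65 on the log2 scale, from 20.7 ± 2.18 to 3.29 ± 1.6 CPM (adjusted p = 9.56e-07). Fcrls, a marker of resident macrophages and microglia (gene 80891; chromosome 3, 87250758 to 87263738, minus strand), fell by 2.43 (adjusted p = 0.000936). The potassium channel subunit gene Kcne3 fell by 2.00, the apelin receptor gene of endothelium Aplnr by 1.74 (gene 23796; chromosome 2, 85136225 to 85139923, plus strand; adjusted p = 0.00702) and Nrep by 1.53.

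Interferon-gamma, presentation, T-cell and NK-cell lists were called higher at day 4 of mXTX301. Of 28 interferon-gamma response genes 24 rose and 0 fell (25 and 0 adjusted over the list alone), Serpina3f by 13.2-fold, and the call held with an estimated correlation (adjusted p = 0.000158). The list level was higher by 1.34 log2 CPM (interval 1.08 to 1.66). All 17 interferon-inducible GTPase genes rose, Gbp4 by 7.09-fold and Gbp6 by 4.26-fold (adjusted p = 0.000274, estimated correlation). In the MHC class I list 15 of 18 rose (16 adjusted over the list alone), among them the peptide transporter Tap1 at 1.63-fold and the immunoproteasome subunit Psmb8 at 1.41-fold (adjusted p = 0.0108, estimated correlation). MHC class II presentation had 8 of 13 higher, including Cd74 at 4.93-fold and H2-DMb1 at 2.40-fold (adjusted p = 0.121, estimated correlation). In the T cell list 16 of 19 rose, Cd3e by 5.37-fold and Cd8b1 by 7.09-fold, while Sit1 fell by 0.85 (17 and 1 adjusted over the list alone; adjusted p = 0.375, estimated correlation). Cytotoxic effectors had 10 of 15 higher, Nkg7 by 4.51-fold and Gzma by 3.71-fold (adjusted p = 0.375, estimated correlation). NK cells had 9 of 12 higher (10 adjusted over the list alone), Klrc1 by 5.42-fold (adjusted p = 0.382, estimated correlation). IL-12 and IL-18 signalling had 11 of 17 higher, Il12rb1 by 2.66-fold and the decoy receptor Il18bp by 3.05-fold, with Gadd45b and Gadd45g lower (13 and 2 adjusted over the list alone; adjusted p = 0.0782, estimated correlation). Inhibitory receptors and ligands had 9 of 14 higher, Pdcd1 by 6.33-fold and Pdcd1lg2 by 4.67-fold, with Lgals9 lower (10 and 1 adjusted over the list alone; adjusted p = 0.355, estimated correlation). mXTX301 replicate 3, the skin-rich one, stood apart in T cell and NK cell levels (2.87 and 2.31), and without it 15 and 7 members were higher. Vehicle replicate 5 stood apart in NK cells (0.67), and without it 10 were higher.

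Myeloid lists rose in part at day 4 of mXTX301. Macrophages had 10 of 18 higher (11 adjusted over the list alone), Fcgr3 by 2.13-fold and Gpnmb by 1.77-fold (adjusted p = 0.54, estimated correlation). Alternatively activated macrophages had 4 of 17 higher, Chil3 by 2.65-fold (adjusted p = 0.542, estimated correlation), and monocytes 7 of 13 higher, Itgam by 2.27-fold, with Cd177 lower (adjusted p = 0.382, estimated correlation). Conventional dendritic cells had 7 of 13 higher, and the cross-presenting subset genes Clec9a and Xcr1 rose 9.75-fold and 7.31-fold (7 and 1 adjusted over the list alone; adjusted p = 0.542, estimated correlation). T cell-attracting chemokines had 4 of 12 higher, Cxcl16 by 1.67-fold (adjusted p = 0.355, estimated correlation). Programmed cell death had 10 of 20 higher and 2 lower, with Casp1 up 1.69-fold and Bax among the lower genes (11 and 2 adjusted over the list alone; adjusted p = 0.121, estimated correlation). Without mXTX301 replicate 3 macrophages had 4 higher and dendritic cells 2; the dendritic cell call was lost without vehicle replicate 4 or mXTX301 replicates 2 or 3.

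Growth, metabolic and endothelial lists were lower at day 4 of mXTX301. Cell cycle genes fell in 21 of 30, Cdk1 by 0.39 and Tyms by 0.49 on the log2 scale (adjusted p = 0.382, estimated correlation). MYC targets and ribosome biogenesis fell in 10 of 20 (adjusted p = 0.496, estimated correlation), and ribosomal proteins in 18 of 28, Rpl18 by 0.42 (19 adjusted over the list alone; adjusted p = 0.496, estimated correlation). Oxidative phosphorylation fell in 17 of 22, Ndufa4 by 0.64 (19 adjusted over the list alone; adjusted p = 0.382, estimated correlation). Cholesterol biosynthesis fell in 13 of 18 (16 adjusted over the list alone; adjusted p = 0.425, estimated correlation). Endothelium fell in 7 of 19, the vascular transcription factor gene Sox18 by 1.12 and the sialomucin gene Emcn by 1.01 (adjusted p = 0.542, estimated correlation). Vehicle replicate 5 stood apart in oxidative phosphorylation (7.76) and ribosomal proteins (10.5); without it the lower members were 11 and 9, and 8 in cholesterol biosynthesis. Endothelium had 4 lower without vehicle replicate 3 or mXTX301 replicate 2 or 4.

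**Figure D1:**
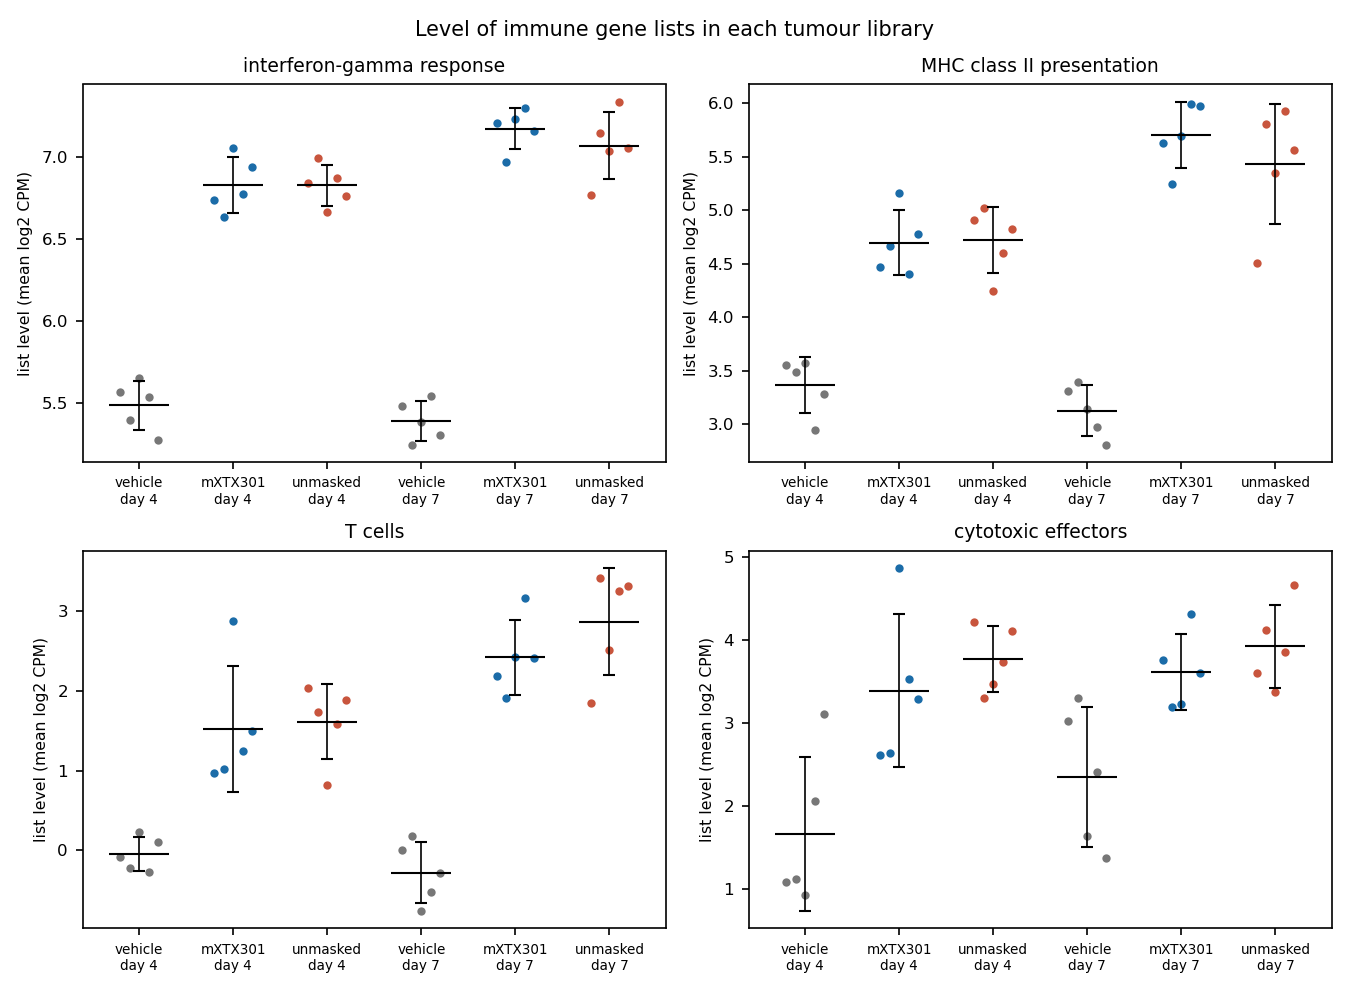
Levels of 4 gene lists (mean log2 CPM of the members) in the 6 groups; points are libraries, lines means and bars SD (n = 5). The mean interferon-gamma response level was 5.49 in vehicle and 6.83 in mXTX301 at day 4, and 5.39 and 7.17 at day 7; T cells stood at -0.28 in vehicle, 2.42 in mXTX301 and 2.86 in the unmasked control at day 7.

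The comparison at day 7 asked whether the masked drug's effect was present 1 week after the dose. MHC class II genes and T-cell genes stood far above vehicle: H2-Ab1, a class II chain gene (gene 14961; chromosome 17, 34257689 to 34269419, plus strand), rose 19.6-fold, from 36.5 ± 9.67 to 715 ± 213 CPM (SD, n = 5; edgeR adjusted p = 1.49e-09). Cd8a rose 20.8-fold, from 1.12 ± 0.56 to 23.5 ± 12 CPM (adjusted p = 1.4e-06), and Cd4, the helper T-cell co-receptor gene also made by some myeloid cells (gene 12504; chromosome 6, 124864692 to 124888221, minus strand), rose 6.17-fold (adjusted p = 1.65e-05). Ifng rose 32.8-fold, to 8.49 ± 3 CPM (adjusted p = 1.36e-07). The killing genes Gzmb (log2 fold change -0.18, adjusted p = 0.738) and Prf1 (adjusted p = 0.208) did not pass, nor did Ncr1 (adjusted p = 0.806). In all, 3985 genes were higher and 3508 lower, 48.4% of those tested, and 1885 and 271 of them changed at least 2-fold. Groups did not overlap in 2560 higher and 2203 lower genes, 30.8%. With the skin-rich libraries left out, 3543 were higher and 3142 lower.

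In the panel 19 genes rose and 1 fell at day 7 of mXTX301 (19 and 1 adjusted over the list alone). Ciita (gene 12265; chromosome 16, 10480059 to 10528418, plus strand) rose 15.9-fold, Ido1 11.4-fold, Cxcl9 7.65-fold (gene 17329; chromosome 5, 92321347 to 92328079, minus strand) and Cd274 5.37-fold. Irf1 rose 2.38-fold, Gbp2 5.11-fold and Socs1 1.92-fold. Il12rb2 rose 12.3-fold and Tbx21 7.46-fold, and the regulatory cytokine gene Il10 rose 3.82-fold (adjusted p = 0.00309). Nos2 and Arg1 rose 7.45-fold and 7.33-fold. Cxcl10 rose 1.44-fold (adjusted p = 0.00858) and the class I gene H2-K1 1.51-fold. The proliferation gene Mki67 fell by 0.38 on the log2 scale (adjusted p = 0.0129). Foxp3 (adjusted p = 0.752), S100a8 (0.157) and Col1a1 (0.108) did not pass. The largest rises were Gbp2b at 125-fold, the lincRNA gene Mirt2 at 41.8-fold, Apol7c, an apolipoprotein L gene of dendritic cells, at 41.7-fold, Gbp10 at 34.5-fold and Ifng. Large falls included Gad1, a glutamate decarboxylase gene, by 3.73 (adjusted p = 0.00148), Pde9a by 2.98, the melanophilin gene Mlph by 2.63 and Mest by 2.40.

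The interferon-gamma, GTPase, presentation and interleukin-12 lists were called higher at day 7 of mXTX301, also with an estimated correlation. Interferon-gamma response had 25 of 28 higher (25 adjusted over the list alone; adjusted p = 0.000379, estimated correlation), with a level difference of 1.78 (interval 1.58 to 1.98). All 17 interferon-inducible GTPase genes were higher, Gbp4 by 10.4-fold (adjusted p = 0.00278, estimated correlation). MHC class I had 17 of 18 higher, Tap1 by 1.77-fold, with Erap1 not passing (adjusted p = 0.00297, estimated correlation). MHC class II had 11 of 13 higher (12 adjusted over the list alone), H2-Aa by 20.3-fold and Cd74 by 18.4-fold (adjusted p = 0.0272, estimated correlation), and its level differed by 2.58 (interval 2.1 to 3.03). IL-12 and IL-18 signalling had 14 of 17 higher and 2 lower, Il18bp by 5.44-fold (adjusted p = 0.0461, estimated correlation).

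T-cell and NK-cell lists at day 7 of mXTX301 were called with the preset correlation and by fry, and not with an estimated correlation. T cells had 18 of 19 higher, Cd3d by 10.0-fold and Cd8b1 by 17.8-fold (adjusted p = 0.172, estimated correlation); the level differed by 2.69 (interval 2 to 3.45). Cytotoxic effectors had 6 of 15 higher, Nkg7 by 7.08-fold and Ctsw by 5.79-fold (adjusted p = 0.542, estimated correlation), and NK cells 6 of 12, Klrk1 by 4.62-fold and Klrc1 by 7.28-fold (8 and 1 adjusted over the list alone; adjusted p = 0.542, estimated correlation). Regulatory T cells had 8 of 13 higher, Ctla4 by 3.98-fold and Ikzf4 by 3.61-fold (adjusted p = 0.303, estimated correlation). Inhibitory receptors and ligands had 13 of 14 higher, Pdcd1 by 9.62-fold and Entpd1, which encodes CD39, by 5.16-fold, while Lgals9 fell by 0.44 (adjusted p = 0.151, estimated correlation). T cell-attracting chemokines had 8 of 12 higher, Ccl5 by 2.40-fold and Cxcl16 by 3.38-fold (adjusted p = 0.172, estimated correlation). Lymphoid aggregate chemokines had 4 of 5 higher (5 adjusted over the list alone), the B-cell attractant gene Cxcl13 by 15.9-fold (adjusted p = 0.197, estimated correlation). The NK cell call was lost without vehicle replicate 5.

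Myeloid lists were called higher at day 7 of mXTX301. Macrophages had 17 of 18 higher, Cd68 by 3.21-fold and Fcgr3 by 4.71-fold, with Pf4 not passing (adjusted p = 0.197, estimated correlation). Alternatively activated macrophages had 9 of 17 higher, Stab1 by 2.91-fold (adjusted p = 0.444, estimated correlation). Monocytes had 10 of 13 higher (11 adjusted over the list alone), Ly6i by 16.4-fold (adjusted p = 0.245, estimated correlation). Neutrophils had 7 of 14 higher, Mmp8 by 13.6-fold and Csf3r by 6.63-fold (adjusted p = 0.303, estimated correlation). Acute inflammatory cytokines had 11 of 14 higher, Il1a by 13.9-fold and Tnf by 3.59-fold (adjusted p = 0.172, estimated correlation), and conventional dendritic cells 9 of 13, Xcr1 by 17.5-fold (adjusted p = 0.338, estimated correlation). Programmed cell death had 11 of 20 higher and 3 lower, with the pyroptosis gene Gsdmd up 1.95-fold (adjusted p = 0.151, estimated correlation). Cell cycle genes fell in 28 of 30, Plk1 by 0.72 and Kif20a by 0.69 (adjusted p = 0.0743, estimated correlation). MYC targets and ribosome biogenesis fell in 10 of 20 (adjusted p = 0.542, estimated correlation), and cholesterol biosynthesis in 17 of 18, Sqle by 0.72 (adjusted p = 0.248, estimated correlation). Alternatively activated macrophages had 5 higher without mXTX301 replicate 5.

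**Figure D2:**
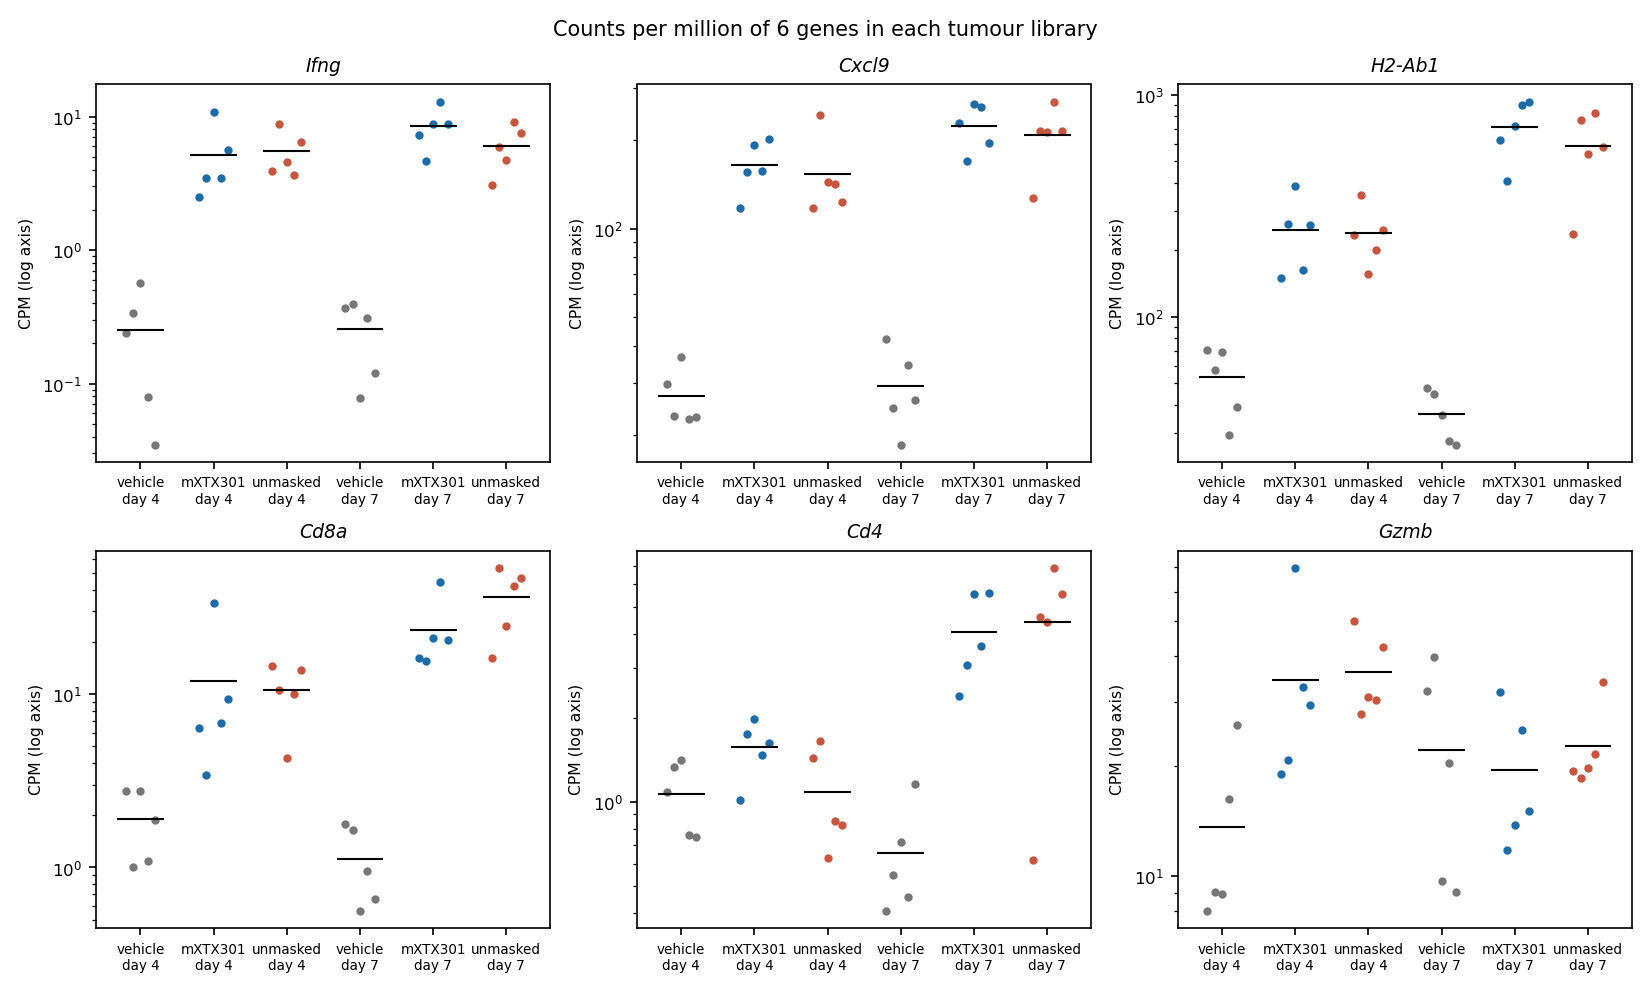
CPM (counts scaled by library size) of 6 panel genes on a log axis in the 6 groups; points are libraries and lines are means (n = 5). Mean Ifng was 0.251 CPM in vehicle at day 4 and 8.49 CPM in mXTX301 at day 7.

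The unmasked control against vehicle at day 4 asked which response an active interleukin-12 gave in the same tumours. Interferon-gamma and its targets were again the leading rises: Ifng rose 21.8-fold, to 5.48 ± 2.15 CPM (SD, n = 5; edgeR adjusted p = 3.05e-06), and Gbp2b 77.4-fold, to 19.9 ± 13.9 CPM. Aplnr fell by 3.76 on the log2 scale, from 7.49 ± 3.26 to 0.555 ± 0.189 CPM (adjusted p = 1.72e-05). In all, 1800 genes were higher and 1665 lower, 22.4% of those tested, and 455 and 210 of them changed at least 2-fold. Groups did not overlap in 1130 higher and 1013 lower genes, 13.8%. Without the skin-rich libraries the counts were 1434 higher and 1325 lower.

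In the panel 20 genes rose and 0 fell at day 4 of the unmasked control (22 and 0 adjusted over the list alone). Cxcl9 rose 5.71-fold, Ciita 6.69-fold, H2-Ab1 4.46-fold (adjusted p = 4.76e-05) and H2-K1 1.24-fold (adjusted p = 0.00384). Cd8a rose 5.6-fold (adjusted p = 0.00144), Gzmb 2.67-fold (adjusted p = 0.0161), Prf1 3.95-fold (adjusted p = 0.00764) and Ncr1 2.78-fold (adjusted p = 0.0291). The neutrophil gene S100a8 rose 4.57-fold (adjusted p = 0.0103). Cd4 (adjusted p = 0.979), Cxcl10 (0.0511), Il10 (0.0927), Foxp3 (0.415), Mki67 (0.972) and Col1a1 (0.418) did not pass. Besides Gbp2b and Ifng, the largest rises were Gbp10 at 17.1-fold, Serpina3f at 15.6-fold and Mirt2 at 15.6-fold. After Aplnr, the largest falls were Fcrls by 3.73, Mest by 3.56, to 1.76 ± 0.53 CPM, Kcne3 by 3.04 and the endothelial protocadherin gene Pcdh12 by 2.35 (adjusted p = 4.75e-06).

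Interferon-gamma, presentation, T-cell and NK-cell lists were called higher at day 4 of the unmasked control. Interferon-gamma response had 23 of 28 higher (24 adjusted over the list alone; adjusted p = 2.75e-05, estimated correlation), all 17 GTPase genes were higher (adjusted p = 7.52e-05, estimated correlation), and MHC class I had 16 of 18 higher, Tap1 by 1.80-fold (17 adjusted over the list alone; adjusted p = 0.000334, estimated correlation). MHC class II had 9 of 13 higher, Cd74 by 5.09-fold (adjusted p = 0.0607, estimated correlation). T cells had 15 of 19 higher, Cd3e by 5.13-fold (16 and 1 adjusted over the list alone; adjusted p = 0.239, estimated correlation). Cytotoxic effectors had 10 of 15 higher, Gzma by 4.68-fold (12 adjusted over the list alone; adjusted p = 0.2, estimated correlation), and NK cells 10 of 12, Klrc1 by 6.05-fold (adjusted p = 0.281, estimated correlation). IL-12 and IL-18 signalling had 8 of 17 higher, Il18bp by 3.17-fold, with Gadd45b lower (10 and 2 adjusted over the list alone; adjusted p = 0.0607, estimated correlation). Inhibitory receptors and ligands had 8 of 14 higher, Pdcd1 by 6.23-fold, with Lgals9 lower (9 and 1 adjusted over the list alone; adjusted p = 0.226, estimated correlation). T cell-attracting chemokines were called higher with Cxcl9 alone above and Ccl12 below (5 and 1 adjusted over the list alone; adjusted p = 0.304, estimated correlation).

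Stromal and myeloid lists at day 4 of the unmasked control moved apart. Endothelium fell in 12 of 19, Sox18 by 1.5 and the VEGF receptor gene Kdr by 1.42 (14 adjusted over the list alone; adjusted p = 0.332, estimated correlation), and its level was lower, with a difference of -0.92 (interval -1.33 to -0.604). The type I interferon list, genes induced by interferon-alpha and -beta, fell in 11 of 22 and rose in 0, Mx1 by 0.90 and Usp18 by 0.78 (0 and 14 adjusted over the list alone; adjusted p = 0.46, estimated correlation). Macrophages had 4 of 18 higher (5 adjusted over the list alone; adjusted p = 0.541, estimated correlation), monocytes 5 of 13, with Cd177 lower (6 and 1 adjusted over the list alone; adjusted p = 0.56, estimated correlation), and neutrophils 7 of 14, Mmp8 by 6.42-fold, with Cd177 lower by a log2 fold change of -3.02 (8 and 1 adjusted over the list alone; adjusted p = 0.46, estimated correlation). Programmed cell death had 10 of 20 higher and 2 lower, Casp1 up 1.74-fold, Casp8 and Bax down (12 and 4 adjusted over the list alone; adjusted p = 0.0745, estimated correlation). Cell cycle fell in 8 of 30, Tyms by 0.46 (11 adjusted over the list alone; adjusted p = 0.541, estimated correlation), MYC targets and ribosome biogenesis in 5 of 20 (adjusted p = 0.541, estimated correlation) and cholesterol biosynthesis in 7 of 18 (8 adjusted over the list alone; adjusted p = 0.52, estimated correlation). The monocyte call was lost without any 1 of 5 libraries and the neutrophil call without any 1 of 3, among them vehicle replicate 5.

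**Figure D3:**
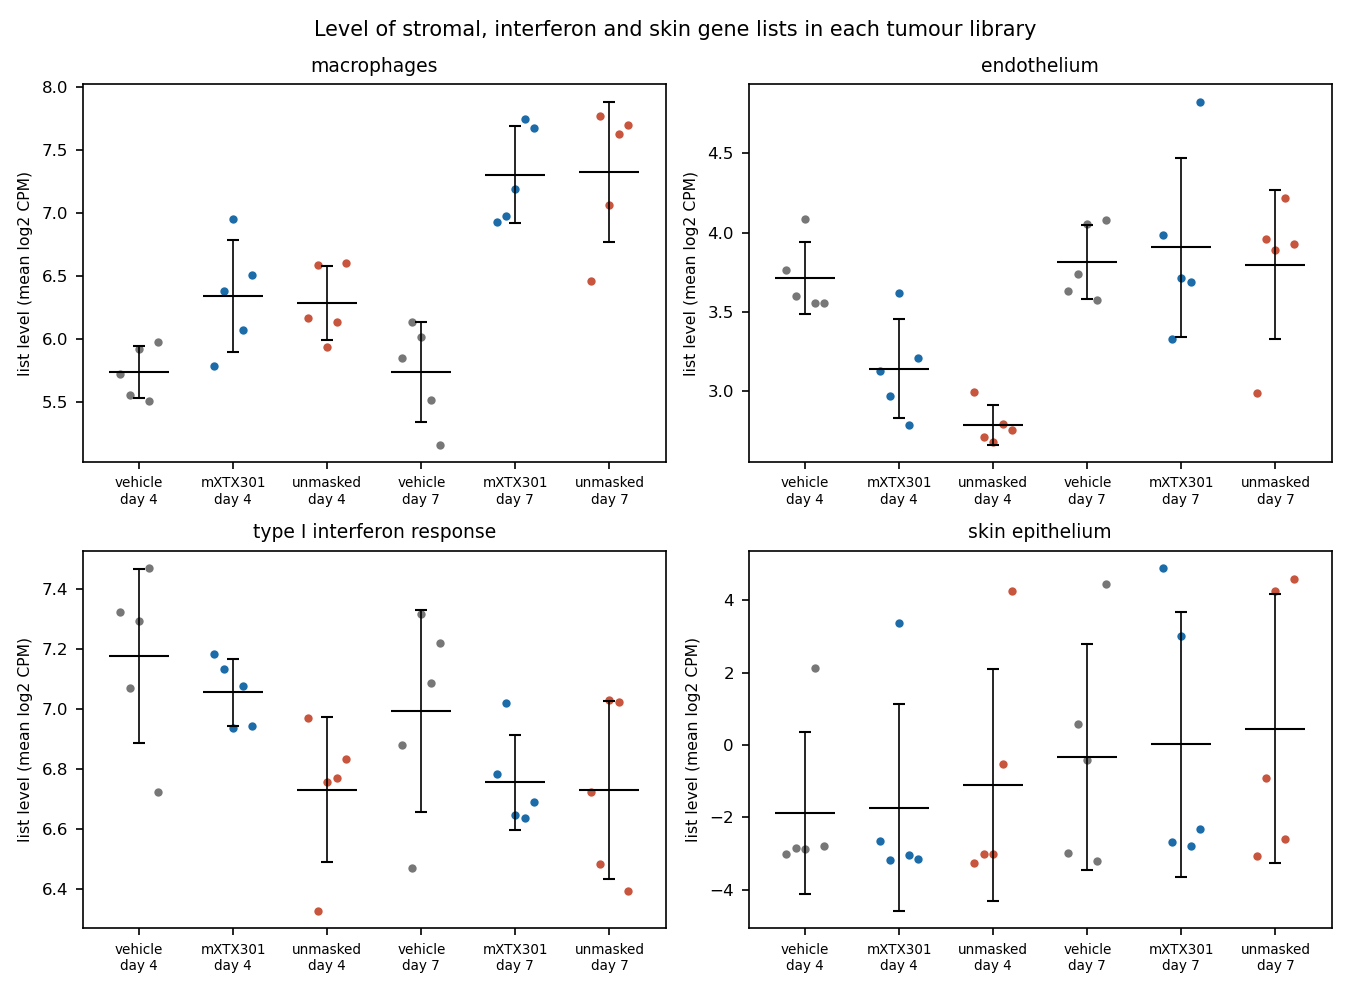
Levels of 4 gene lists (mean log2 CPM of the members) in the 6 groups; points are libraries, lines means and bars SD (n = 5). Mean endothelium levels at day 4 were 3.71 in vehicle, 3.14 in mXTX301 and 2.79 in the unmasked control.

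At day 7 the unmasked control was compared with vehicle for the later response. Cd8a rose 32.3-fold, from 1.12 ± 0.56 to 36.5 ± 15.6 CPM (SD, n = 5; edgeR adjusted p = 3.96e-07), H2-Ab1 rose 16.2-fold, to 590 ± 232 CPM, and Cd4 rose 6.71-fold (adjusted p = 1.19e-05). Ifng rose 23.4-fold (adjusted p = 5.54e-07). T-lineage genes were among the largest rises, with the signalling gene Themis at 52.5-fold and the chemokine receptor gene Cxcr6 at 36.1-fold. In all, 3595 genes were higher and 3378 lower, 45% of those tested, and 1748 and 193 of them changed at least 2-fold. Groups did not overlap in 1939 higher and 1978 lower genes, 25.3%. Without the skin-rich libraries the counts were 2998 higher and 2802 lower.

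In the panel 21 genes rose and 0 fell at day 7 of the unmasked control (21 and 0 adjusted over the list alone). Ciita rose 13-fold, Ido1 10.9-fold, Cxcl9 7.10-fold, Nos2 6.62-fold, Arg1 6.15-fold, Cd274 5.11-fold and Gbp2 4.03-fold. Il12rb2 rose 20.3-fold and Tbx21 8.71-fold. Prf1 rose 2.47-fold (adjusted p = 0.0384), S100a8 4.43-fold (adjusted p = 0.00451), Il10 3.48-fold (adjusted p = 0.00571) and Cxcl10 1.35-fold (adjusted p = 0.0312). Gzmb (adjusted p = 0.962), Ncr1 (0.522), Foxp3 (0.841), Mki67 (0.166) and Col1a1 (0.44) did not pass. Gbp2b rose 79.6-fold, Apol7c 66.0-fold and Mirt2 38.2-fold. The largest falls were the cytoskeletal gene Shroom2 by 3.07 on the log2 scale (adjusted p = 0.000967), Fcrls by 2.65, Mest by 2.34 and the cartilage collagen genes Col9a2 and Col11a1 by 2.17 and 2.07.

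Interferon-gamma, presentation, T-cell and NK-cell lists were called higher at day 7 of the unmasked control. Interferon-gamma response had 25 of 28 higher (26 adjusted over the list alone; adjusted p = 0.00056, estimated correlation), GTPases 17 of 17 (adjusted p = 0.00592, estimated correlation) and MHC class I 17 of 18 (adjusted p = 0.00592, estimated correlation). MHC class II had 11 of 13 higher, H2-Aa by 16.8-fold (adjusted p = 0.0327, estimated correlation), and IL-12 and IL-18 signalling 14 of 17, Il18r1 by 23.9-fold (adjusted p = 0.0327, estimated correlation). T cells had 18 of 19 higher, Cd3e by 15.9-fold (adjusted p = 0.0976, estimated correlation), with a level difference of 3.14 (interval 2.13 to 4). Inhibitory receptors and ligands had 13 of 14 higher, Lag3 by 3.80-fold, with Lgals9 lower (adjusted p = 0.0976, estimated correlation). Cytotoxic effectors had 7 of 15 higher, Ctsw by 9.52-fold (adjusted p = 0.453, estimated correlation), and NK cells 8 of 12, Klre1 by 6.91-fold (adjusted p = 0.428, estimated correlation). Regulatory T cells had 8 of 13 higher, Ctla4 by 4.52-fold (9 adjusted over the list alone; adjusted p = 0.314, estimated correlation). T cell-attracting chemokines had 8 of 12 higher, Ccl5 by 2.65-fold (adjusted p = 0.153, estimated correlation), and lymphoid aggregate chemokines 4 of 5, Ltb by 9.78-fold (5 adjusted over the list alone; adjusted p = 0.185, estimated correlation).

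Myeloid lists at day 7 of the unmasked control were called. Macrophages had 18 of 18 higher, Cd68 by 3.37-fold (adjusted p = 0.153, estimated correlation), and alternatively activated macrophages 6 of 17, Stab1 by 2.94-fold (adjusted p = 0.476, estimated correlation). Monocytes had 7 of 13 higher, Ly6i by 13.2-fold, with Cd177 lower (8 and 1 adjusted over the list alone; adjusted p = 0.428, estimated correlation). Neutrophils had 9 of 14 higher, Mmp8 by 19.3-fold, with Cd177 lower (adjusted p = 0.185, estimated correlation). Acute inflammatory cytokines had 10 of 14 higher, Il1a by 15.6-fold (adjusted p = 0.153, estimated correlation), and conventional dendritic cells 6 of 13, Xcr1 by 14.7-fold (7 adjusted over the list alone; adjusted p = 0.428, estimated correlation). Mast cells had 6 of 10 higher, Cpa3 by 3.64-fold (7 and 1 adjusted over the list alone; adjusted p = 0.476, estimated correlation). Programmed cell death had 10 of 20 higher and 3 lower, Gsdmd up 1.76-fold (11 and 3 adjusted over the list alone; adjusted p = 0.207, estimated correlation). The mast cell call was lost without either of 2 libraries, and the programmed cell death call without any 1 of 4.

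Growth and metabolic lists at day 7 of the unmasked control were lower. Cell cycle genes fell in 25 of 30, Plk1 by 0.58 (27 adjusted over the list alone; adjusted p = 0.0976, estimated correlation), MYC targets and ribosome biogenesis in 11 of 20 (adjusted p = 0.509, estimated correlation) and cholesterol biosynthesis in 18 of 18, Cyp51 by 0.85 (adjusted p = 0.153, estimated correlation). Oxidative phosphorylation fell in 10 of 22, Ndufa4 by 0.43 (11 adjusted over the list alone; adjusted p = 0.644, estimated correlation). The type I interferon list fell in 9 of 22, Usp18 by 0.61, while Herc6 rose 1.41-fold (adjusted p = 0.698, estimated correlation). Skeletal muscle was called higher with Neb alone past the threshold, at 5.26-fold (adjusted p = 0.0425; adjusted p = 0.698, estimated correlation). The type I interferon call was lost without any 1 of 4 libraries, and the skeletal muscle call without any 1 of 5.

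The change of each drug effect from day 4 to day 7 asked whether the response grew or waned. The mXTX301 effect on H2-Ab1 grew by 2.09 on the log2 scale (edgeR adjusted p = 0.0156), on Cd4 by 2.07 ± 0.57 (SE, adjusted p = 0.0382) and on H2-K1 by 0.40 (adjusted p = 0.0322). Its effect on Ifng did not differ past the threshold (0.67, adjusted p = 0.585), nor did those on Cd8a (1.72, adjusted p = 0.146), Gzmb (-1.52, adjusted p = 0.114), Prf1 (-1.19, adjusted p = 0.299) and Mki67 (-0.56, adjusted p = 0.0578). In all, 302 genes changed upward and 470 downward, 4.99% of those tested, and in the panel 3 and 0 (6 and 2 adjusted over the list alone). The largest upward changes were the serine protease gene Prss46 (2.84, adjusted p = 0.00487), the inflammasome cytokine gene Il1b (2.29, adjusted p = 0.0156) and the myeloid lectin gene Clec4d (2.24, adjusted p = 0.0272). Large downward changes included the cartilage matrix gene Cilp (-2.10, adjusted p = 0.0374) and Pcdhb16 (-1.45). Leaving out the skin-rich libraries gave 595 and 788. Single libraries moved these counts, to 48 to 437 upward (48 without mXTX301 day 7 replicate 4) and 146 to 803 downward (146 without mXTX301 day 7 replicate 5).

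For the unmasked control the effect on Cd4 grew by 2.73 (edgeR adjusted p = 0.0177), on Cd8a by 2.53 (adjusted p = 0.0441) and on H2-Ab1 by 1.86 (adjusted p = 0.0253). Ifng (0.10, adjusted p = 0.941), Gzmb (-1.39, adjusted p = 0.133) and Prf1 (-0.68, adjusted p = 0.575) did not pass. In all, 457 genes changed upward and 341 downward, 5.15% of those tested, and in the panel 3 and 0 (3 and 0 adjusted over the list alone). The largest upward changes were Apol7c (4.43, adjusted p = 0.0325), Aplnr (3.42, adjusted p = 0.0177) and the matrix gene Fmod (3.26, adjusted p = 0.0429), and the largest downward changes Tex11 (-2.96), the adhesion receptor gene Adgrl3 (-2.06) and Acsm3 (-2.02). With the skin-rich libraries left out these were 73 and 52. Leaving out single libraries gave 71 to 1301 upward (71 without unmasked day 7 replicate 2, 1301 without vehicle day 4 replicate 5) and 57 to 1724 downward (57 without vehicle day 7 replicate 4, 1724 without vehicle day 4 replicate 5).

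Lists whose mXTX301 effect changed between days included MHC class II with 6 of 13 upward, H2-Aa by 2.04 and Cd74 by 1.90 (9 adjusted over the list alone; adjusted p = 0.428, estimated correlation). Acute inflammatory cytokines had 2 of 14 upward, Il1b and Lif (4 adjusted over the list alone; adjusted p = 0.428, estimated correlation), and cell cycle 8 of 30 downward, Bub1b by a log2 fold change of -0.67 (21 adjusted over the list alone; adjusted p = 0.428, estimated correlation). For the unmasked control MHC class II had 5 of 13 upward (7 adjusted over the list alone), T cells 3 of 19, namely Cd4, Cd5 and Cd8a (15 adjusted over the list alone), endothelium 3 of 19, namely Aplnr, Mmrn2 and Sox18 (11 adjusted over the list alone), and cell cycle 6 of 30 downward (21 adjusted over the list alone); each had adjusted p = 0.486 with an estimated correlation. Dissociation and early stress had 4 of 18 upward for mXTX301, Fos by 1.73, Atf3 by 1.24 and Dusp1 by 1.18 (6 adjusted over the list alone; adjusted p = 0.428, estimated correlation), and 3 of 18 for the unmasked control (6 adjusted over the list alone; adjusted p = 0.486, estimated correlation). Adipocytes were called upward for both drugs (adjusted p = 0.502 and 0.672 with an estimated correlation) and skeletal muscle for the unmasked control (adjusted p = 0.502, estimated correlation). In all 22 lists were called for mXTX301 and 19 for the unmasked control, and 0 of either with an estimated correlation, where fry gave 6 and 10.

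The direct comparison of mXTX301 with the unmasked control asked whether the masked and unmasked forms differed in the tumour; the doses differed, 0.39 against 0.03 mg/kg. The interferon-gamma response level differed by 0.00 at day 4 (interval -0.238 to 0.269) and by 0.10 at day 7 (interval -0.178 to 0.435). Ifng differed by -0.08 ± 0.46 on the log2 scale at day 4 (SE; edgeR adjusted p = 0.949) and by 0.48 at day 7 (adjusted p = 0.91). MHC class II levels differed by -0.02 at day 4 (interval -0.507 to 0.527) and 0.28 at day 7 (interval -0.322 to 1.18), and T cell levels by -0.09 (interval -0.923 to 1.13) and -0.45 (interval -1.33 to 0.578). With edgeR 0 genes were higher and 0 lower on either day. At day 4 2092 genes had an unadjusted p under 0.05, 13.5% of those tested, and the lowest adjusted p was 0.0954; the DESeq2 Wald test called 13 higher and 12 lower, and a fit of only the groups compared called 89 and 105. At day 7 there were 898 such genes, 5.8%, with a lowest adjusted p of 0.227, and the DESeq2 Wald test called 7 and 7. A missed threshold does not show that the drugs acted alike: the simulated test recovered 76.1% of 2-fold changes on each day. Panel counts were 0 and 0 on both days (0 and 0 adjusted over the list alone).

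Groups did not overlap between the drugs in 371 higher and 533 lower genes at day 4, 5.84% against 0.794% by chance, and in 86 and 121 at day 7, 1.34%. Among named genes with larger differences, none past the threshold, were Aplnr (2.02, adjusted p = 0.251), Clec9a (1.48, adjusted p = 0.255) and the neutrophil gene Retnlg (-1.78, adjusted p = 0.255) at day 4, and Retnlg (-2.58, adjusted p = 0.257) and Cd8a (-0.63, adjusted p = 0.9) at day 7. At day 4 4 lists were called higher and 5 lower, with 0 members past the threshold: type I interferon response was higher (level difference 0.33, interval 0.106 to 0.75; adjusted p = 0.88, estimated correlation), as was endothelium (0.36, interval -0.0038 to 0.859; adjusted p = 0.962, estimated correlation), and oxidative phosphorylation was lower (-0.18, interval -0.282 to -0.0996; 9 lower adjusted over the list alone; adjusted p = 0.88, estimated correlation). At day 7 9 lists were called higher and 5 lower, among them GTPases higher (0.29, interval -0.0101 to 0.558; adjusted p = 0.624, estimated correlation), T cells lower (adjusted p = 0.843, estimated correlation) and erythroid cells lower, where unmasked day 7 replicate 4 stood apart at 3.91 against 1.93 to 2.49 in its group (adjusted p = 0.383, estimated correlation). With an estimated correlation 0 lists passed on either day, fry gave 0, and 0 exact level tests passed after adjustment. Without the skin-rich libraries 0 genes passed on either day.

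The similarity of the drug responses was read across genes, which are not independent replicates. Differences from vehicle correlated with r = 0.812 at day 4 and 0.908 at day 7, and 81.4% and 89% of genes had the same sign. Shared vehicle libraries raise r: simulations without a drug effect gave 0.493 and 0.496, and with separate vehicle libraries, 2 or 3 per drug, r was 0.567 on average at day 4 (0.272 to 0.759) and 0.737 at day 7 (0.604 to 0.816). The covariance was 0.215 and 0.556, against 0.0438 and 0.0537 in the simulations. At day 4 1511 genes were higher under both drugs, where independent calls would share 291, and 1148 lower, where they would share 266. At day 7 these were 3167 and 2798, against 925 and 765. Independent calls are not the value without an effect, because both sets of calls used the same vehicle libraries; that value was not computed for the overlaps or for opposite calls. Under both drugs on either day 0 genes were called in opposite directions.

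**Figure D4:**
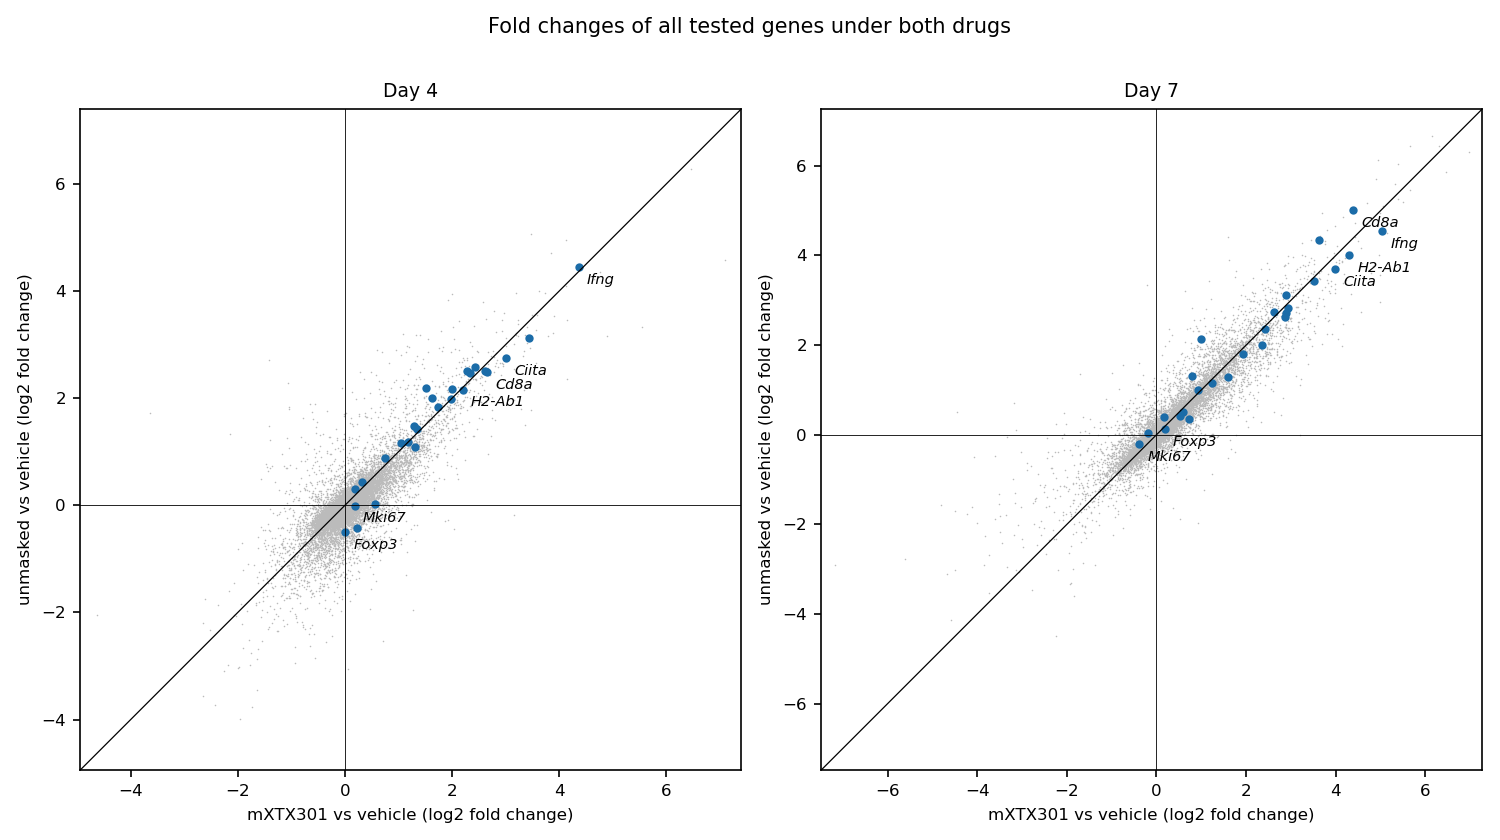
Log2 fold changes against vehicle of 15482 genes for mXTX301 (x) and the unmasked control (y) at day 4 and day 7; panel genes are blue and the line marks equality. These fold changes had r = 0.805 and 0.917, with vehicle libraries shared by both axes.

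The comparison of vehicle at day 7 with day 4 asked what changed in tumours without drug. With edgeR 3 genes were higher and 3 lower: Arhgap5, a gene for a small-GTPase regulator, rose 1.41-fold, Dctn1 1.20-fold and Dcaf5 1.18-fold, and the RNA polymerase subunit gene Polr2g fell by 0.34 on the log2 scale, Slx1b by 0.32 and the nucleoside transporter gene Slc29a1 by 0.31 (all adjusted p = 0.0491). Of the panel 0 rose and 0 fell (0 and 1 adjusted over the list alone), with Irf1 at -0.26 (adjusted p = 0.0637) and Gzmb at 0.70 (adjusted p = 0.354). In 2932 genes, 18.9%, the unadjusted p was under 0.05, and groups did not overlap in 147 higher and 169 lower genes, 2.04% against 0.794% by chance. The count depended on the tool, with 308 higher and 296 lower by the DESeq2 Wald test and 26 and 51 by limma-voom. Without the skin-rich libraries 213 were higher and 248 lower. For lists 2 were called higher, cytotoxic effectors and cholesterol biosynthesis, and 8 lower, among them type I interferon response, regulatory T cells, MYC targets (8 lower adjusted over the list alone) and glycolysis and hypoxia; each had adjusted p = 0.912 with an estimated correlation, and fry called 0.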

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

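The dilution tests for the type I interferon and endothelium lists, and the fits without skin-rich libraries and with covariates, were chosen after the results were seen. In 396 groups of 5 libraries, of list levels, panel genes and total counts, 35 held a library far from the other 4, where chance gives about 1 in 20 groups.

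Lymphocyte lists held several such libraries (levels are mean log2 CPM). Replicate 3 of mXTX301 at day 4 stood at 2.87 for T cells (others 0.967 to 1.5), at 2.31 for NK cells (others 0.553 to 0.966) and at 1.81 for plasmacytoid dendritic cells (others 0.253 to 0.701). Vehicle day 4 replicate 5 stood at 0.67 for NK cells (others -0.734 to -0.416). In the unmasked control at day 7, replicate 1 stood at 0.81 for regulatory T cells (others 1.61 to 1.82) and replicate 4 at 0.373 for B cells and plasma cells (others -0.857 to -0.587).

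Myeloid lists held others. For alternatively activated macrophages, mXTX301 day 4 replicate 1 stood at 1.19 (others 2.25 to 2.56) and vehicle day 7 replicate 3 at 2.52 (others 0.292 to 0.859). For monocytes, vehicle day 4 replicate 3 stood at 4.4 (others 3.52 to 3.76) and unmasked day 4 replicate 5 at 4.45 (others 4.03 to 4.15). For neutrophils, vehicle day 4 replicate 3 stood at -0.106 (others -0.937 to -0.739), mXTX301 day 4 replicate 3 at 0.461 (others -0.537 to -0.277) and unmasked day 4 replicate 5 at 0.882 (others -0.142 to 0.128). For mast cells, vehicle day 7 replicate 1 stood at -1.16 (others 0.0223 to 0.306).

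In lists of growth, metabolism and other tissues, vehicle day 4 replicate 5 stood at 7.76 for oxidative phosphorylation (others 7.21 to 7.32) and at 10.5 for ribosomal proteins (others 9.83 to 9.97). Vehicle day 4 replicate 2 stood at 5.44 for programmed cell death (others 5.54 to 5.58). Replicate 1 of mXTX301 at day 4 stood at 7.41 for cell cycle (others 7.18 to 7.24) and at 7.18 for oxidative phosphorylation (others 7.1 to 7.12). Unmasked day 7 replicate 1 stood at 2.99 for endothelium (others 3.89 to 4.22), and unmasked day 4 replicate 2 at -1.9 for skeletal muscle (others 2.19 to 3.14) and 2.01 for erythroid cells (others 1.16 to 1.34). Unmasked day 7 replicate 4 stood at 3.91 for erythroid cells (others 1.93 to 2.49). For skin epithelium, vehicle day 4 replicate 4 stood at 2.14 (others -3 to -2.79) and mXTX301 day 4 replicate 3 at 3.38 (others -3.17 to -2.66).

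Panel genes also held such libraries (log2 CPM). In the unmasked control, Cxcl9 at 7.93 in day 4 replicate 2 (others 6.88 to 7.18), Socs1 at 5.24 in day 7 replicate 1 (others 5.72 to 5.89), Cd4 at -0.621 in day 7 replicate 1 (others 2.15 to 2.79) and Gzmb at 5.08 in day 7 replicate 5 (others 4.22 to 4.43). In mXTX301, Ciita stood at 5.01 in day 7 replicate 2 (others 5.51 to 5.63), Cd8a at 5.48 in day 7 replicate 4 (others 3.96 to 4.39) and Col1a1 at 9.39 in day 4 replicate 1 (others 9.62 to 9.71). In vehicle, S100a8 stood at 2.4 in day 7 replicate 5 (others -0.845 to -0.19) and Mki67 at 7.9 in day 4 replicate 5 (others 8.71 to 8.96).

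These drug effects differed between the days when tested. For mXTX301 the list levels changed, by exact permutation tests, by 0.44 for interferon-gamma response (adjusted p = 0.0422), 0.286 for MHC class I (adjusted p = 0.00921), 1.26 for MHC class II (adjusted p = 0.0151), 1.35 for lymphoid aggregate chemokines (adjusted p = 0.0408), 1.1 for acute inflammatory cytokines (adjusted p = 0.0422), 0.502 for migratory dendritic cells (adjusted p = 0.0477) and -0.279 for cell cycle (adjusted p = 0.00921). Its panel genes were Cd4 (2.07), H2-Ab1 (2.09) and H2-K1 (0.401), among 302 genes changed upward and 470 downward (as few as 48 and 146 without 1 library). For the unmasked control 0 list levels passed (lowest adjusted p 0.0528). Its changes in these lists, in that order, were 0.337, 0.165, 0.955, 1.27, 1.14, 0.467 and -0.276, not tested against those of mXTX301. Panel genes of the unmasked control were Cd4 (2.73), Cd8a (2.53) and H2-Ab1 (1.86), among 457 genes upward and 341 downward (71 to 1301 and 57 to 1724 without 1 library).

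Skin transcripts stood out in 8 of the 30 libraries, with a skin epithelium level of at least 2.14 against at most 0.582 in the other 22. Krt14 reached 28.2 to 341 CPM in these libraries against at most 17.8 CPM elsewhere, and Krt10 28.2 to 323 CPM against 7.13 CPM. All 8 also held hair follicle transcripts above the highest level elsewhere (-4.03 to -3.47 against -4.1 or less), as skin left on the dissected tumour would give. These levels lie near the floor, with 5 of 21 members past the low-count filter, and vehicle day 4 replicate 4, at -4.03, cleared the others narrowly. Sebaceous gland transcripts were likewise above the others in 8 of 8 (-1.3 to -0.612 against -1.57 or less), which argues against keratinocyte genes made by the tumour cells themselves. No other biological explanation was tested, and skin-rich libraries occurred in every group.

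At day 4 of the unmasked control the type I interferon list was called lower with the preset correlation (median log2 fold change -0.439) but not with an estimated correlation (adjusted p = 0.46), while the interferon-gamma list rose. Library scaling was argued against by medians of -0.442 with DESeq2 factors and -0.462 with upper-quartile factors, and a single high vehicle library by a median of -0.378 or lower without any of the 5 vehicle libraries in turn. Dilution of tumour cell transcripts by infiltrating cells could not be told apart from regulation: the change in the T cell level effect between days was 1.48 and did not pass after adjustment (exact permutation p = 0.00554, adjusted p = 0.0528), with 3 of 19 genes upward (15 adjusted over the list alone), while the change in the type I list effect was 0.182 (exact permutation p = 0.489, adjusted p = 0.658, 63504 regroupings), too imprecise to decide. A drop in type I interferon signalling in tumour or host cells may also underlie it and was not tested.

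The endothelium list was called lower at day 4 with the preset correlation, with 7 of 19 genes lower for mXTX301 and 12 for the unmasked control, but not with an estimated correlation (adjusted p = 0.542 and 0.332). It was not called lower at day 7, although the change of the list level between days did not pass (0.907 with adjusted p = 0.0819 for the unmasked control, 0.662 with adjusted p = 0.172 for mXTX301). Less skin and muscle on the dissected tumours was argued against by a median of -0.747 in the unmasked control and -0.59 in mXTX301 with skin and muscle levels as covariates (9 and 4 genes lower), and by -0.772 and -0.802 without the skin-rich libraries. Dilution by infiltrating immune cells was not decided. Endothelium minus fibroblast levels differed by -0.693 in the unmasked control (exact permutation p = 0.0159) and by -0.732 in mXTX301 (p = 0.00794). Fibroblast levels may also have moved (-0.231 and 0.163), so they are no fixed reference. An early loss of vessels or endothelial transcripts after interleukin-12 is a hypothesis from the same data. Cell counts were not analysed.

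Other splits of the same libraries tested whether chance can be excluded for the gene counts. As many genes as the real split gave were called in 1 split for mXTX301 against vehicle at day 4 (real 4982, highest other 2527), 1 at day 7 (7493, highest other 3096), 1 for the unmasked control at day 4 (3465, highest other 1851) and 1 at day 7 (6973, highest other 5113). Chance can be excluded there and for the unmasked change between days, with 1 split (798, highest other 350). It cannot be excluded for vehicle over time, with 6 (6, highest other 3150). The mXTX301 change lay in between, with 4 (772, highest other 1262). That share of the 100 splits is under the 0.05 fixed beforehand, but another split called more genes than the real one. Between the drugs the real count was 0 on either day, so all 100 splits gave as many (highest other 1 at day 4 and 218 at day 7) and say nothing about chance there. Splits that called 3150 and 218 genes, far above the real counts, point to a structure of the samples that the groups do not give.

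For the number of lists called with the preset correlation, chance cannot be excluded in any comparison. As many were called in 21 splits for mXTX301 at day 4 (real 21, highest other 26), 36 at day 7 (22, highest other 28), 29 for the unmasked control at day 4 (19, highest other 28) and 20 at day 7 (26, highest other 31). Between the drugs there were 83 at day 4 (9, highest other 28) and 66 at day 7 (14, highest other 27). There were 62 for vehicle over time (10, highest other 21), 11 for the change of the mXTX301 effect (22, highest other 30) and 21 for that of the unmasked control (19, highest other 26).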

How the results depend on the processing

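Fits without skin-rich libraries or with covariates were added after seeing the data. In the comparisons of each drug with vehicle, gene counts stayed within 1.5 times under every alternative except for the unmasked control at day 4, where 1055 genes were lower when only the groups compared were fitted. Across named genes, 33065 alternative values kept their side of the threshold, 555 newly passed and 1339 no longer passed. For list tests these numbers were 5741, 257 and 394, and for list levels 540, 1 and 5. Counts of list members stayed within 1.5 times in 14964 cases and moved further in 1338. Of the list levels, 76 passed the exact test, and 73 to 75 under alternatives. The largest shift of the median of all genes under any scaling was 0.0656.

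With an estimated correlation the number of lists called was 3 and 5 for mXTX301 at days 4 and 7, 3 and 5 for the unmasked control, and 0 in the comparisons of the drugs, of vehicle over time and of effects between days. With fry 0 were called between the drugs or for vehicle over time, and 6 and 10 for the changes of the mXTX301 and unmasked effects.

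Between the drugs, 89 genes were higher and 105 lower at day 4 when only the groups compared were fitted, and 13 and 12 by DESeq2; at day 7 DESeq2 gave 7 and 7. For vehicle over time the counts were 0 and 0 with DESeq2 size factors, with no filter, with only the groups compared and with covariates, 34 and 51 with upper-quartile factors, 46 and 94 with the 1 CPM filter, 54 and 32 with a replicate block, 308 and 296 by DESeq2, 26 and 51 by limma-voom, 25 and 66 on the authors' table and 213 and 248 without the skin-rich libraries. For the change of the mXTX301 effect, upward genes were 162 with no filter, 600 by DESeq2, 184 by limma-voom, 176 with only the groups compared and 595 without the skin-rich libraries; downward genes were 874 by DESeq2 and 788 without the skin-rich libraries. For the unmasked effect, upward genes were 269 with no filter, 985 by DESeq2, 276 by limma-voom, 187 with only the groups compared and 73 without the skin-rich libraries; downward genes were 204 with no filter, 737 by DESeq2, 100 with only the groups compared and 52 without the skin-rich libraries. The cause was not tested. The similarity of the drug responses was 0.848 and 0.928 with the 1 CPM filter, which leaves 13171 genes, and 0.567 and 0.737 with the vehicle libraries split, which removes the sharing and also leaves fewer vehicle libraries per drug; these were not separated.

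Signs or sides reversed in 6 values. Krt10 without the skin-rich libraries had log2 fold changes of -1.38 for mXTX301 and -1.62 for the unmasked control at day 7 (2.36 and 2.08 with all libraries, past no threshold), and the cholesterol list between the drugs at day 7 had adjusted p = 0.591 in the other direction. With covariates the skeletal muscle list reversed with adjusted p = 0.665 for the unmasked control at day 7, 0.492 between the drugs at day 7 and 0.728 for the change of the unmasked effect. Removing muscle and skin levels does this by construction.

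Leaving out each library in turn gave 1994 to 2450 higher and 1972 to 2725 lower genes for mXTX301 at day 4 (20 to 25 lists), 3343 to 3946 and 3299 to 3864 at day 7 (22 to 26 lists), 1474 to 2101 and 1205 to 1757 for the unmasked control at day 4 (18 to 24 lists) and 3082 to 3679 and 2932 to 3665 at day 7 (23 to 27 lists). Between the drugs the counts were 0 to 0 at day 4 (6 to 13 lists) and 0 to 2 higher and 0 to 3 lower at day 7, where mXTX301 day 7 replicate 3 gave the highest (12 to 19 lists). Similarity was 0.725 to 0.828 at day 4, lowest without unmasked day 4 replicate 2 and 0.744 without mXTX301 day 4 replicate 3. At day 7 it was 0.858 to 0.924, lowest without mXTX301 day 7 replicate 1, 0.88 without mXTX301 day 7 replicate 3 and 0.883 without unmasked day 7 replicate 4.

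For vehicle over time the counts were 0 to 536 higher and 0 to 539 lower (7 to 12 lists). They were 0 and 0 without day 4 replicates 1 or 3 or day 7 replicates 1, 2 or 4, 36 and 56 without day 4 replicate 2, 59 and 100 without day 4 replicate 4, 187 and 265 without day 4 replicate 5, 171 and 99 without day 7 replicate 3 and 536 and 539 without day 7 replicate 5. For the change of the mXTX301 effect the counts were 48 to 437 upward and 146 to 803 downward (18 to 27 lists). Upward counts were 124 and 123 without vehicle day 4 replicates 1 and 3, 145, 177 and 57 without vehicle day 7 replicates 1, 2 and 4, 59, 137 and 83 without mXTX301 day 4 replicates 1, 2 and 4, and 48 and 54 without mXTX301 day 7 replicates 4 and 5. Downward counts were 255 without vehicle day 4 replicate 1, 803, 150 and 737 without vehicle day 7 replicates 3, 4 and 5, 161 and 249 without mXTX301 day 4 replicates 1 and 4, and 157 and 146 without mXTX301 day 7 replicates 4 and 5.

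For the change of the unmasked effect the counts were 71 to 1301 upward and 57 to 1724 downward (15 to 24 lists). Upward and downward counts were 151 and 97, 221 and 174, 184 and 196, and 1301 and 1724 without vehicle day 4 replicates 1, 2, 3 and 5. Without vehicle day 7 replicate 1 there were 292 upward, without replicate 3 663 downward, and without replicates 2, 4 and 5 218 and 168, 81 and 57, and 881 and 759. Without unmasked day 4 replicates 1 to 4 they were 287 and 219, 756 and 895, 137 and 163, and 119 and 88. Without unmasked day 7 replicates 1, 2, 4 and 5 they were 1194 and 880, 71 and 61, 108 and 85, and 152 and 129. Single libraries thus moved the gene counts for vehicle over time and for changes between days by more than 1.5 times.

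Depth was 48.3 M counts or more per library; a gene at 0 counts is limited to 3 reads, and low-count genes below the filter, such as Ccl19 and Cxcr5, could not be compared.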

Other observations

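Some lists outside the lymphocyte and interferon programmes had members that changed. Erythroid cells held 5 measured genes and Epor, the erythropoietin receptor gene, fell in each drug comparison with vehicle, by 0.79 and 1.12 for mXTX301 and by 0.83 and 0.86 for the unmasked control on the log2 scale at days 4 and 7. In the unmasked control at day 7 the red-cell genes Slc4a1 and Alas2 rose 21.2-fold (adjusted p = 0.000805) and 10.8-fold (adjusted p = 0.00602), so the list median was -0.239 and the mean 1.27. Replicate 4 of that group stood apart for the list; without it the log2 fold change of Slc4a1 dropped from 4.40 to 2.45 and that of Alas2 from 3.43 to 0.69, which no longer passed. Mast cell genes rose at day 7: Kit, the stem cell factor receptor gene, rose 2.37-fold and 2.49-fold, the protease genes Cpa3 3.55-fold and 3.64-fold and Cma1 3.16-fold and 3.33-fold, for mXTX301 and the unmasked control. For mXTX301 at day 7 6 of 10 mast cell genes rose, the list was not called (adjusted p = 0.0986) and its level differed by 0.956 (exact permutation, adjusted p = 0.0147). Adipocyte genes were led by Cd36, a fatty acid transporter also made by macrophages, at 2.92-fold and 7.52-fold for mXTX301 and 3.20-fold and 7.12-fold for the unmasked control; the list was not called (adjusted p = 0.599, 0.0573, 0.754 and 0.171 in that order).

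B cells and plasma cells held 8 measured genes that went apart: Cd22 rose 2.19-fold and 4.25-fold for mXTX301 and 5.85-fold at day 7 of the unmasked control, while the B-cell receptor gene Cd79a fell by 0.71 and 0.83 for mXTX301. Counts were 1 higher and 1 lower, 3 and 2, 0 and 1, and 2 and 1, and the list was not called (adjusted p = 0.908, 0.702, 0.853 and 0.735). Plasmacytoid dendritic cells went apart too, with Pacsin1 up 4.03-fold and Siglech down by a log2 fold change of -2.66 at day 4 of mXTX301 (adjusted p of the list = 0.599). Migratory dendritic cells were not called (adjusted p = 0.635, 0.0755, 0.75 and 0.0868): Cd86 rose 1.96-fold, 4.43-fold, 1.82-fold and 4.09-fold, while the actin-bundling gene Fscn1 fell by 0.39, 0.55, 0.31 and 0.50. Epithelial markers were not called (adjusted p = 0.644, 0.921, 0.569 and 0.948), with the colon keratin gene Krt20 lower by log2 fold changes of -2.19, -2.10, -2.99 and -1.72 and the tight junction gene Tjp3 up 2.41-fold at day 4 of mXTX301.

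Further lists were not called for either drug. Glycolysis and hypoxia had adjusted p = 0.759 and 0.161 for mXTX301 and 0.948 and 0.566 for the unmasked control, with Hif1a up 1.23-fold, 1.32-fold, 1.16-fold and 1.36-fold and its target Ankrd37 lower, at log2 fold changes of -0.80, -0.82, -0.80 and -0.73. Unfolded protein response had adjusted p = 0.0649, 0.332, 0.523 and 0.171, with Pdia6 at -0.30 at day 4 of mXTX301. Fibroblasts and collagen had adjusted p = 0.599, 0.168, 0.129 and 0.326, with Mmp2 up 3.06-fold and Col6a2 at -1.20 at day 7 of mXTX301. Dissociation and early stress had adjusted p = 0.242, 0.107, 0.0659 and 0.192, with the immediate-early gene Ier2 at -0.61 on both days of mXTX301 and Atf3 up 3.36-fold at day 7. Skin epithelium had adjusted p = 0.973, 0.894, 0.554 and 0.94, with 0 members past the threshold. For mXTX301 the type I interferon list was not called (adjusted p = 0.233 and 0.056), with 1 higher and 4 lower at day 4 and 2 and 12 at day 7 (7 lower without vehicle day 7 replicate 3); Oas1a fell by 0.51 and 0.61 and Herc6 rose 1.44-fold and 1.5-fold. At day 4 regulatory T cells (adjusted p = 0.0559) and lymphoid aggregate chemokines (adjusted p = 0.0914) were not called for mXTX301, with 4 of 13 and 3 of 5 higher, nor were neutrophils (adjusted p = 0.197) and acute inflammatory cytokines (adjusted p = 0.137), with 3 higher each.

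Median, mean and test differed in sign for some lists. Skin epithelium had medians of 1.19 and 0.291 for mXTX301 at days 4 and 7 where the test pointed down, as did skeletal muscle at day 7 (median 1.2) and between the drugs at day 4 (median 0.317). Erythroid cells at day 7 of mXTX301 had a median of -0.363 and a mean of 0.0922. Plasmacytoid dendritic cells at day 4 of the unmasked control had a median of 0.0675 and a mean of -0.169, B cells and plasma cells there a median of -0.109 and a mean of 0.0171, and endothelium at day 7 a median of 0.0182 where the test pointed down. Interferon-gamma response between the drugs at day 4 had a median of -0.0804 and a mean of 0.0164, and lymphoid aggregate chemokines between the drugs at day 7 a median of -0.29 where the test pointed up. For vehicle over time IL-12 and IL-18 signalling had a mean of 0.138 where the test pointed down. Unfolded protein response (mXTX301 at day 7 and the unmasked control on both days) and glycolysis and hypoxia (both drugs at day 4) had medians and means of opposite sign.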
